A study of Mus musculus with 12 samples.

How the data were processed

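Gene expression was measured in the tongue of mouse embryos at embryonic day 13.5 on the C57BL/6J background, with 1 Affymetrix Mouse Genome 430 2.0 array per sample. The 12 samples fell into 2 genotypes by their labels. Control embryos carried the Myf5-Cre transgene with 1 floxed and 1 wild-type copy of Smad4, and mutant embryos carried Myf5-Cre with both copies floxed, so that Cre recombinase made under the control of the muscle gene Myf5 removes Smad4 from the lineage that expresses it. Each genotype had 6 arrays that the labels call biological replicates. Litter, the number of tongues per sample and the scan batch are not given in the sources used here, so no named batch could be tested. A free-text field of the labels describes embryos of another kind and was not used.

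The deposited values were summaries per probe set on a log2 scale, made by the authors with RMA, per the submitters' processing notes. RMA subtracts background, normalises between arrays and combines the probes of a probe set. Its software and version are not given in the sources used here, nor is the base of the logarithm. Base 2 was taken from the range of the values, which ran from 2.57 to 15.09. Array medians lay between 6.09 and 6.17, and no further normalisation was applied. RMA forces the arrays to nearly the same distribution, so a shift shared by most genes would not be seen. It also compresses changes of dim probe sets, whose fold changes are then understated. Array signals carry no counting depth, and the number of arrays limits the precision.

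Of the 45101 probe sets, 64 control probe sets were left out of the tests. The GEO platform annotation gave 1 gene symbol for 34945 probe sets, several for 932 and none for 9160. Symbols of 34741 probe sets were checked through the gene identifier against RefSeq names of assembly GRCm38.p6, and none changed. Genes were named only from probe sets with 1 symbol. Each of 18194 genes was represented by its brightest probe set over all 12 arrays, a choice that ignores genotype; 9009 genes had more than 1 probe set. The array annotation carried no genome build used here, so no coordinates are given.

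Mutant and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, genotype as the only term, 2-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. A second count added a fold of at least 1.5. The test was checked on simulated data for the mutant against control comparison over 18194 genes. It recovered 90% of genes changed by 0.5 on the log2 scale and 99% of those changed by 1, and 4.06% of its calls were unchanged genes. The simulated genes varied independently and with equal spread in both groups. These rates therefore do not cover correlated genes, unequal spread or structure among the arrays, as real data may have.

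The design, 25 gene lists and the rule for named genes were fixed before the data were examined. The lists held 8 groups of muscle and signalling genes, 7 other pathways and 10 sets of markers of cell types or sex, and 508 of their 536 entries were measured. Each list was summarised by its median log2 fold change, the members that passed, and limma's camera test against all other genes with a preset inter-gene correlation of 0.01, adjusted over the 25 lists. Camera was run again with an estimated correlation and on ranks, and fry tested whether members moved one way. The mean of each list on each array was compared between genotypes by an exact 2-sided permutation test, whose smallest possible p is 0.00216, as were array medians, 3′ to 5′ differences of control probe sets and sex-linked genes. Named genes were 9 chosen beforehand (Smad4, Myf5, Myod1, Myog, Myf6, Pax7, Fgf6, Fgf4 and Cdh15), the 8 largest rises and 8 largest falls among passing genes, and up to 4 passing members of each muscle or signalling list and 2 of each other list by smallest p. Where a list had no passing member, the one with the smallest p is given as values. Genes named outside this rule are said to be so.

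The alternatives were quantile normalisation, centring of arrays on their medians, the mean of all probe sets of a gene, every probe set on its own, leaving out dim probe sets (mean under 6.13, the median of all probe sets), a trended and robust variance, array weights, the replicate number as a block, a covariate for sex, an unequal-variance test per gene, and each array left out in turn. Leaving out 3 sets of arrays was added after the data were seen. These were control 3, mutant 4 and mutant 6 (signal of both sexes), control 6 and mutant 6 (low 18S signal), and mutants 1 and 2 (farthest from the controls on the first principal component). No arrays were duplicates: correlations between arrays ran from 0.991 to 0.997, and at most 0.149% of probe sets had identical values in a pair.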

Results

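The tongue of the mouse embryo at embryonic day 13.5 was profiled on 12 arrays to ask how gene expression changes when Smad4, the shared signal transducer of the TGF-β and BMP pathways, is removed from the Myf5-expressing muscle lineage. Arrays of 6 mutant samples were set against those of 6 control samples from embryos that kept 1 working copy of Smad4. Whole tongue RNA was measured, so each value averages muscle with mesenchyme, epithelium, nerve and vessels. Values are log2 signals, given as mean ± SD with n = 6 in each group, and adjusted p values come from limma.

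Smad4 itself was near the same level in both groups. Its brightest probe set read 12.29 ± 0.07 in controls and 12.14 ± 0.27 in mutants, a difference of −0.15 ± 0.10 (SE, adjusted p = 0.427). The other Smad4 probe sets differed by −0.07 and −0.15. Mutant 1 alone lay apart, at 11.58, while the other mutants were between 12.18 and 12.30. Without mutant 1 the brightest probe set differed by −0.04. Whether these probe sets lie in the deleted part of the gene is not given in the sources used here, and other cells of the tongue keep Smad4, so the probe sets do not check the genotype.

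Genes of the skeletal muscle programme were lower in the mutant tongue, and Fgf6, a growth factor made by embryonic muscle, fell most. Fgf6 went from 8.68 ± 0.30 in controls to 6.59 ± 0.93 in mutants, 4.28-fold lower (adjusted p = 0.00178). It was followed by Myf5, the determination factor under whose control the Cre is made (−1.81 ± 0.20 SE on the log2 scale), Ankrd1, an ankyrin repeat protein of striated muscle (−1.67 ± 0.26), Sln, the sarcolipin that inhibits the calcium pump of the sarcoplasmic reticulum (−1.63 ± 0.15), and Col22a1, a collagen of the muscle-tendon junction (−1.60 ± 0.18). The remaining largest falls were Calcb (−1.56), which encodes a calcitonin gene-related peptide, Slc44a3 (−1.55) and the uncharacterised 2310002L09Rik (−1.54). The last differed by −0.999 without mutants 1 and 2 (adjusted p = 0.0576).

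The largest rise was of Aldh1a1, an enzyme that makes retinoic acid, from 4.80 ± 0.18 to 6.47 ± 0.64, 3.19-fold higher (adjusted p = 0.000725). Snap25, a protein of synaptic vesicle fusion, rose by 1.51 ± 0.18 (SE) on the log2 scale. The other large rises were of 2610528A11Rik (1.47), Foxd4, a forkhead factor (1.34), Pcp4, a calmodulin-binding neuronal peptide (1.28), Cdhr1, a cadherin-related protein (1.10), Gpr50 (1.09) and Npr3, the clearance receptor of natriuretic peptides (1.08). Most of these rises began from dim probe sets. In controls Aldh1a1, Snap25, 2610528A11Rik, Foxd4, Cdhr1 and Gpr50 read 4.63 to 5.62, under the median of all probe sets (6.13). Foxd4 and Cdhr1 stayed under it in mutants, at 5.97 and 5.83. A second probe set of Gpr50, nearly as bright in controls (5.58 against 5.61), differed by 0.12 and did not pass. Without mutants 1 and 2 the difference was 0.92 for Foxd4 (adjusted p = 0.0745) and 1.53 for 2610528A11Rik (0.0654), which was above every control on 3 of 6 mutant arrays. Without control 6 and mutant 6, 2610528A11Rik differed by 1.18 (adjusted p = 0.0648). In an unequal-variance test the adjusted p was 0.0916 for Foxd4, 0.0600 for 2610528A11Rik, 0.0504 for Gpr50 and 0.0866 for 2310002L09Rik.

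In all, 2020 of 18194 genes passed, 1147 higher and 873 lower in the mutant, and 4509 had an unadjusted p under 0.05. With a fold of at least 1.5 the balance turned to falls, with 267 genes lower and 128 higher. At least 2-fold, 70 genes were lower and 9 higher. The groups did not overlap for 1146 of the 18194 genes, or 6.30%, where chance gives 0.216%. The first principal component, with 35% of the variance, held all mutants above all controls, with mutants 1 and 2 farthest at 24.7 and 20.3 and mutants 5 and 3 nearest at 2.90 and 7.11. Without mutants 1 and 2, 875 genes passed (379 higher), and without control 3, mutant 4 and mutant 6, whose sex-linked signals were mixed, 836 passed. Without those 3 arrays Foxd4 and 2310002L09Rik differed by 1.29 and −1.58 and lost their calls (adjusted p = 0.0952 and 0.0936), with fewer samples tested. Leaving out mutant 1 or mutant 2 alone reduced the genes higher in the mutant to 733 and 763.

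**Figure D1:**
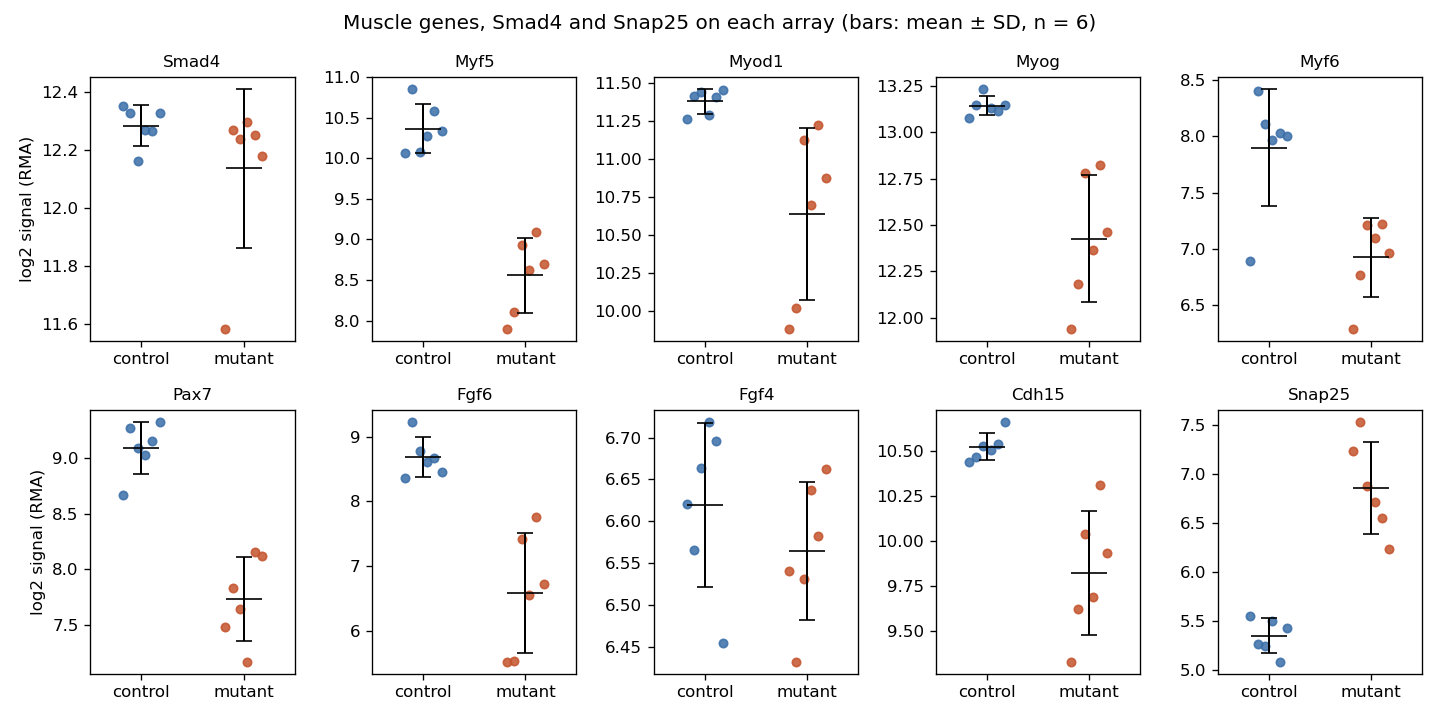
Log2 signal (vertical axis) of the 9 genes chosen beforehand and Snap25 on each of the 6 control (blue) and 6 mutant (orange) arrays, with bars at the mean ± SD; each panel has its own scale. Myf5 lies near 10.37 in controls and 8.56 in mutants without overlap, Snap25 rises from 5.35 to 6.86, and Smad4 and the Fgf4 probe set shown overlap between groups.

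All measured myogenic determination and differentiation factors of the Myf5 family fell. Of 19 myogenic regulatory factors and cofactors, 15 fell and none rose, with a median of −0.56 (camera adjusted p = 5.48e-13; adjusted p = 0.0555 with an estimated correlation). Adjusted over the list alone, 16 fell and 1 rose. Myf5 went from 10.37 ± 0.30 to 8.56 ± 0.47, while Myf6 fell by 0.97, Myod1 by 0.74 and Myog, which drives terminal differentiation, by 0.72 on the log2 scale. Smyd1, a muscle histone methyltransferase, fell by 1.02, Cdkn1a, a cell cycle inhibitor induced in differentiating myoblasts, by 0.60, and Tead4 by 0.38. The mean of the list was below every control array on 6 of 6 mutant arrays (exact permutation p = 0.00216, the smallest possible). Myod1 was the least secure of these, with an adjusted p of 0.0304. Without the 3 arrays of mixed sex-linked signal it differed by −0.80 (adjusted p = 0.110) and Myf6 by −0.98 (adjusted p = 0.0786). Leaving out 1 array ended the Myod1 call in 8 of 12 cases, and without mutants 1 and 2 Myod1 fell by 0.40 (adjusted p = 0.0330) and Myf6 differed by −0.78 (adjusted p = 0.0734). In an unequal-variance test the adjusted p was 0.134 for Myod1 and 0.0524 for Myf6.

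Genes of muscle progenitors were lower on balance. Of 18 measured, 8 fell and 1 rose, with a median of −0.42 (camera adjusted p = 5.91e-05; adjusted p = 0.179 with an estimated correlation), and 12 fell and 4 rose when adjusted over the list alone. Pax7, which marks myogenic progenitors, fell from 9.09 ± 0.23 to 7.73 ± 0.38, and its other probe set fell by 1.26. Dbx1 fell by 1.08, the transcriptional coactivator Eya2 by 0.76 and the Notch effector Heyl by 0.63. The member that rose was Eya1 (0.56), named after its value was seen. The mean of the list was −0.70 and −0.68 on mutants 1 and 2 against −0.39 to −0.19 on the other mutants, and without these 2 arrays the median was −0.22 (camera adjusted p = 0.000629).

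Contractile genes fell nearly as a block. Of 51 measured sarcomere and contractile genes 40 fell and none rose, 45 when adjusted over the list alone, with a median of −0.73, a 1.66-fold reduction (camera adjusted p = 2.23e-40; adjusted p = 0.0437 with an estimated correlation). Myoz1, a Z-disc protein, fell by 1.01 on the log2 scale, Klhl40, which stabilises thin filament proteins, by 0.90, Xirp1, an actin-binding protein, by 0.87, and Myl4, the embryonic myosin light chain, by 0.66 from the high level of 13.69 ± 0.14.

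Genes of excitation-contraction coupling, the neuromuscular junction and muscle metabolism were lower. Of 35 measured, 27 fell and none rose, with a median of −0.78 (camera adjusted p = 3.05e-27; adjusted p = 0.0437 with an estimated correlation), and 28 fell and 1 rose when adjusted over the list alone. Sln went from 12.85 ± 0.24 to 11.22 ± 0.33. Pygm, muscle glycogen phosphorylase, fell by 1.03, Cacna1s, the calcium channel of the T-tubule, by 0.99, and myoglobin (Mb) by 0.74 on the log2 scale. Each of these 4 genes was below every control on 6 of 6 mutant arrays by its brightest probe set. A dimmer second Mb probe set differed by −0.07 (adjusted p = 0.634 over all probe sets). The marker lists of neurons (median 0.71), cranial mesenchyme (0.37), oral epithelium (0.26) and cartilage and bone (0.22) lay higher in the same mutant arrays.

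Genes of myoblast fusion and adhesion changed in both directions. Of 35 measured, 8 fell and 2 rose, with a median of −0.02 (camera adjusted p = 0.0963), and 10 fell and 5 rose when adjusted over the list alone. Those that fell included the muscle cadherin Cdh15, from 10.52 ± 0.08 to 9.82 ± 0.35, Cav3, the muscle caveolin (−0.81), Tanc1 (−0.54) and the integrin Itga9 (−0.39). The risers were Cdh2 (0.39) and Dock5 (0.32), named after their values were seen. The mean of the list was −0.10 ± 0.04 in mutants and 0 ± 0.07 in controls (exact permutation p = 0.0152, adjusted p = 0.0316 over the lists), and lay below every control on 2 of 6 mutant arrays. The sign of the median depended on single arrays, and the list passed camera without control 1 (adjusted p = 0.0304), control 4 (0.0427) or mutants 1 and 2 (0.0335).

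**Figure D2:**
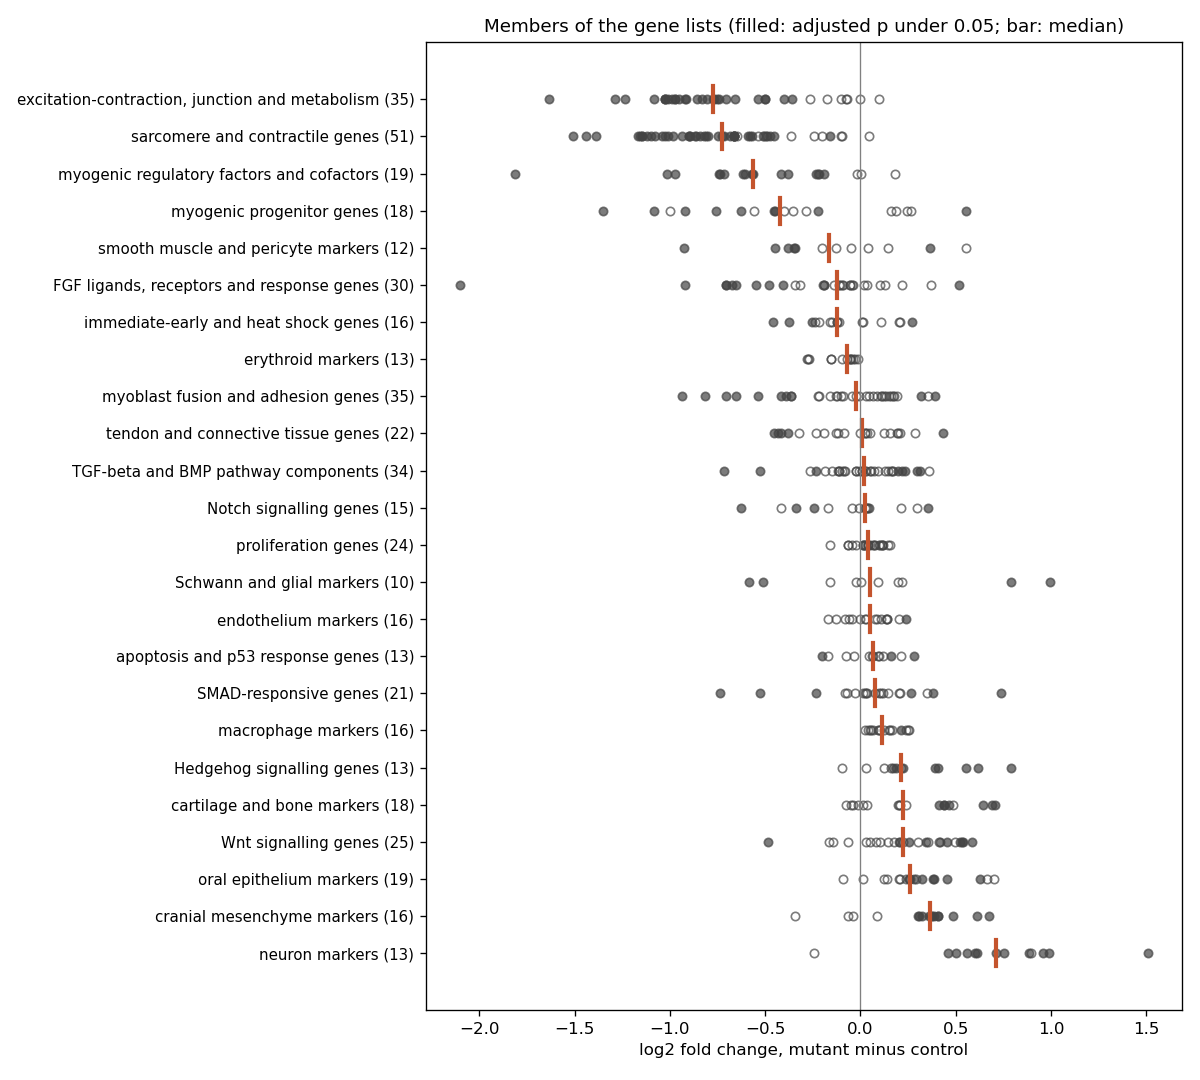
Log2 fold change of each measured member (horizontal axis, mutant minus control, 6 arrays each) of 24 gene lists with the number measured in brackets; filled points passed at an adjusted p under 0.05, and bars mark the list medians. Sarcomere genes centre on −0.73 and neuron markers on 0.71, with most members passing in both lists.

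FGF ligands, receptors and response genes were lower, led by the muscle members. Of 30 measured, 10 fell and 1 rose, with a median of −0.13 (camera adjusted p = 3.95e-06; adjusted p = 0.0437 with an estimated correlation), and 14 fell and 2 rose when adjusted over the list alone. With dim probe sets left out the median was −0.19. Besides Fgf6, the receptor Fgfr4 of muscle progenitors fell from 8.81 ± 0.23 to 7.89 ± 0.27, and the feedback inhibitors Spry2 and Spry1 fell by 0.55 and 0.41. The member that rose was the receptor Fgfr2 (0.52), named after its value was seen. Probe sets of Fgf4 disagreed. The brightest was flat, at 6.62 ± 0.10 against 6.56 ± 0.08 (−0.06, adjusted p = 0.605), while dimmer ones differed by −1.17 (adjusted p = 0.00126 over all probe sets), −0.83 (0.00137) and −0.24 (0.0781).

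Components of the TGF-β and BMP pathways and genes known to respond to SMADs each changed in both directions. Of 34 components, 5 rose and 3 fell, with a median of 0.02 (camera adjusted p = 0.756), and 7 rose and 4 fell when adjusted over the list alone. The BMP antagonists Chrdl1 and Nog fell by 0.71 and 0.53, while Tgfbr3, the betaglycan co-receptor, rose by 0.31 and Ltbp1, which stores latent TGF-β in the matrix, by 0.29. A dim second probe set of Tgfbr3 differed by −0.12 and did not pass. Of 21 SMAD-responsive genes, 3 rose and 3 fell, with a median of 0.08 (camera adjusted p = 0.256), and 4 rose and 3 fell when adjusted over the list alone. Ccn2 and Ccn1, matricellular proteins, fell by 0.74 and 0.53, and Id4 and Msx1, targets of BMP signalling, rose by 0.74 and 0.38. The other Msx1 probe set, nearly as bright (6.93 against 7.01 in controls), was flat (0.04, adjusted p = 0.888 over all probe sets). Other Id4 probe sets differed by 0.78 (0.00403) and 0.26 (0.233). Without the 3 arrays of mixed sex-linked signal Nog differed by −0.47 (adjusted p = 0.0581), Tgfbr3 by 0.31 (0.0725), Ltbp1 by 0.26 (0.0681) and Msx1 by 0.38 (0.0702), with fewer samples tested. Tgfbr3 and Msx1 also lost their calls without mutants 1 and 2, at 0.28 (adjusted p = 0.0741) and 0.31 (0.0900), and with the mean of a gene's probe sets, at 0.10 (0.458) and 0.21 (0.0630).

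Hedgehog genes were higher in the mutant tongue. Of 13 measured, 8 rose and none fell, with a median of 0.22 (camera adjusted p = 5.01e-06; adjusted p = 0.0768 with an estimated correlation), and 10 rose and 1 fell when adjusted over the list alone. Hhip, a target and inhibitor of the pathway, rose from 7.34 ± 0.20 to 8.13 ± 0.30, and Foxf1, a forkhead target in mesenchyme, by 0.62. Of 25 Wnt signalling genes, 9 rose and 1 fell (median 0.22; camera adjusted p = 0.000173; adjusted p = 0.208 with an estimated correlation), and 12 rose and 1 fell when adjusted over the list alone. Lef1, a nuclear effector, rose by 0.52 and the secreted antagonist Frzb fell by 0.49. Of 15 Notch genes, Heyl, Lfng and Notch3 fell and the ligand Jag1 rose by 0.35, with 4 falls and 1 rise adjusted over the list alone. The Notch median of 0.03 and mean of −0.05 differed in sign (camera adjusted p = 0.256), and Lfng and Notch3 are named after their values were seen. With the 3 arrays of mixed sex-linked signal left out, Lef1 differed by 0.41 (adjusted p = 0.0585) and Jag1 by 0.29 (0.0810), and without mutants 1 and 2 Jag1 differed by 0.28 (0.0711). Markers of cranial mesenchyme (median 0.37) and oral epithelium (0.26) lay higher in the same mutant arrays, and the means of the Hedgehog, Wnt and mesenchyme lists were all highest on mutant 1 (0.44, 0.36 and 0.39).

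Markers of several tissues outside muscle were higher, and those of neurons most. Of 13 neuron markers 11 rose and none fell, with a median of 0.71, a 1.64-fold increase (camera adjusted p = 2.41e-10; adjusted p = 0.103 with an estimated correlation), and 12 rose and 1 fell when adjusted over the list alone. Snap25 went from 5.35 ± 0.18 to 6.86 ± 0.47 and Tubb3, neuronal β-tubulin, from 7.70 ± 0.19 to 8.59 ± 0.26. The mean of the list ranged from 0.23 to 1.10 above the control mean over the mutant arrays, beyond all controls on 6 of 6 (exact permutation p = 0.00216). A dim second Snap25 probe set differed by 0.21 and did not pass.

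Of 16 cranial mesenchyme markers, 12 rose and none fell (median 0.37; camera adjusted p = 7.8e-07; adjusted p = 0.103 with an estimated correlation), 12 rising and 1 falling when adjusted over the list alone. The homeobox genes Dlx5 and Prrx1 rose by 0.68 and 0.61. Of 18 cartilage and bone markers, 7 rose and none fell (median 0.22; camera adjusted p = 5.17e-05; adjusted p = 0.0437 with an estimated correlation), 8 over the list alone. The cartilage collagens Col9a2 and Col9a3 rose by 0.69 and 0.64. Of 19 oral epithelium markers, 7 rose and none fell (median 0.26; camera adjusted p = 3.23e-06; adjusted p = 0.264 with an estimated correlation), 10 over the list alone, with the tight junction gene Cldn4 at 0.46 and the epithelial splicing factor Esrp1 at 0.39. Esrp1 differed by 0.40 without the 3 arrays of mixed sex-linked signal (adjusted p = 0.0744) and by 0.29 without mutants 1 and 2 (0.0879). With dim probe sets left out the cartilage and bone median was 0.43.

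**Figure D3:**
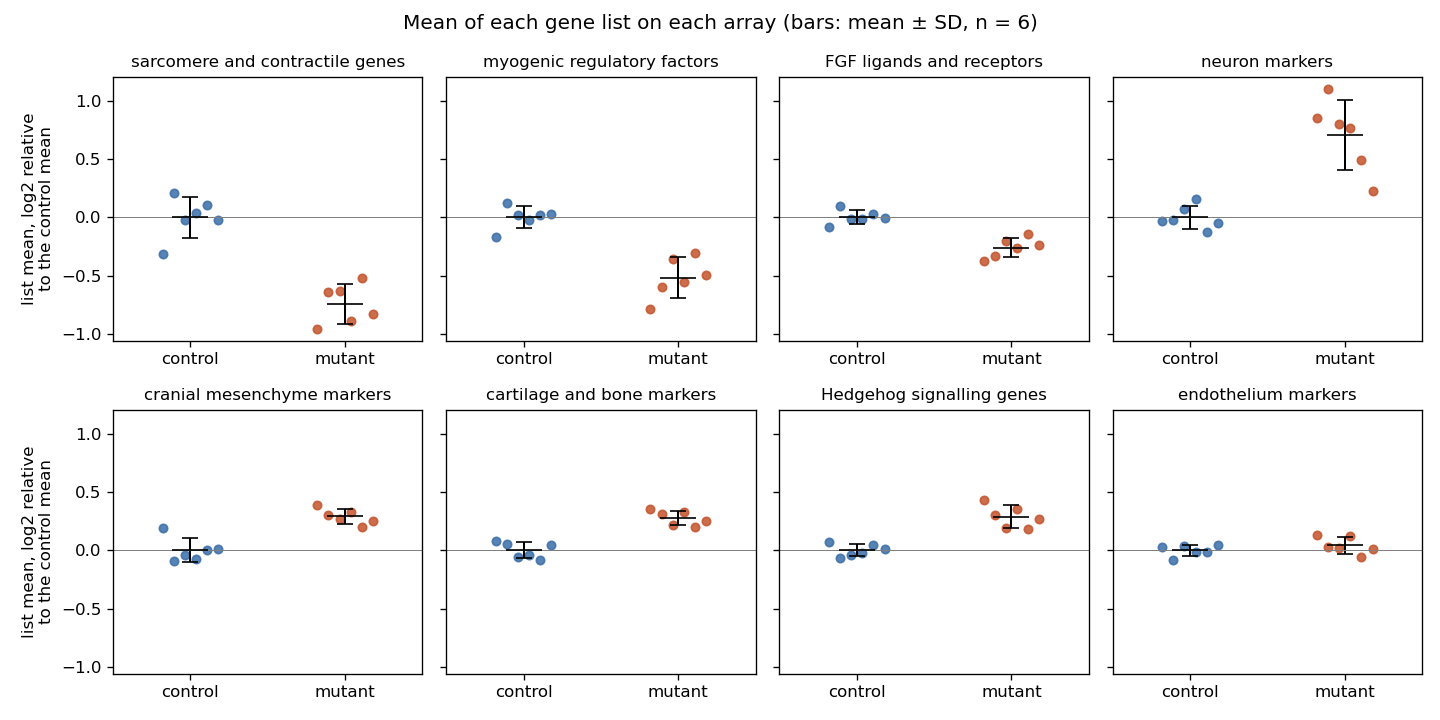
Mean of each of 8 gene lists on each array (vertical axis, log2 relative to the control mean of each gene), for 6 control (blue) and 6 mutant (orange) arrays with bars at the mean ± SD. Sarcomere genes average −0.75 in mutants and neuron markers 0.71, while endothelium markers average 0.04.

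Other cell types shifted little or in both directions. Of 16 endothelium markers only Sox18 rose (0.24; list median 0.05, camera adjusted p = 0.347), with 2 rising over the list alone. Of 16 macrophage markers only Csf1r passed, with a rise (0.21), though all 16 lay above 0. The median was 0.11 (camera adjusted p = 0.00264, and 0.264 with an estimated correlation), with 3 rising over the list alone. The mean of the list was beyond all controls on 5 of 6 mutant arrays (exact permutation p = 0.0130, adjusted p = 0.0295 over the lists). The Csf1r call ended with 8 of the 12 arrays left out singly. That of Sox18 ended without mutant 1 (adjusted p = 0.0516), without mutants 1 and 2 (0.24, adjusted p = 0.0548) and without the 3 arrays of mixed sex-linked signal (0.23, adjusted p = 0.0894). None of 13 erythroid markers passed, over all genes or over the list alone, though all 13 lay below 0. The median was −0.07 (camera adjusted p = 0.0483, and 0.32 with an estimated correlation). The mean of the list did not pass (exact permutation p = 0.0628, adjusted p = 0.0981 over the lists), nor did the list with fry (adjusted p = 0.108). The embryonic globin Hba-x differed by −0.28 (adjusted p = 0.171). The erythroid median was −0.11 without control 2, −0.14 without the 3 arrays of mixed sex-linked signal and −0.12 without control 6 and mutant 6. The list lost its call after quantile normalisation (−0.07, adjusted p = 0.0654) and with dim probe sets left out (−0.16, adjusted p = 0.0609). Of 10 Schwann cell and glial markers, Fabp7 (1.00) and S100b (0.79) rose and Ngfr (−0.59) and Erbb3 (−0.51) fell, with a median of 0.05 (camera adjusted p = 0.858). Over the list alone 2 rose and 3 fell, and S100b and Ngfr are named after their values were seen. Of 12 smooth muscle and pericyte markers 5 fell, among them the actin-binding proteins Tagln (−0.92) and Smtn (−0.34), and 1 rose (Mylk, 0.37, named after its value was seen), with a median of −0.16 (camera adjusted p = 0.00762; adjusted p = 0.264 with an estimated correlation). Over the list alone 6 fell and 2 rose. The smooth muscle list did not pass without control 6 and mutant 6 (median −0.14, adjusted p = 0.0521) or with camera on ranks (adjusted p = 0.0744). Its mean gave an exact permutation p of 0.0346, which did not pass over the lists (adjusted p = 0.0618). Its median was −0.27 with dim probe sets left out.

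None of 24 proliferation genes passed by its brightest probe set, over all genes or over the list alone (median 0.04; camera adjusted p = 0.352), though the list passed camera without control 1 (median 0.0647, adjusted p = 0.0382) and without mutants 1 and 2 (0.0654, adjusted p = 0.0335). Ccne1, with the smallest p, read 11.36 ± 0.10 in controls and 11.20 ± 0.11 in mutants (adjusted p = 0.129). Its other probe set differed by −0.23 (adjusted p = 0.0160 over all probe sets), and Ccne1 passed with the mean of both (−0.19, adjusted p = 0.0205) and without mutant 6 (adjusted p = 0.0381). Of 13 apoptosis and p53 response genes, Bcl2l11 (0.28) and Zmat3 (0.16, named after its value was seen) rose and Apaf1 fell by 0.20 (median 0.07; camera adjusted p = 0.352), with 2 rising and 2 falling over the list alone, the Bcl2l11 call ended with 7 of the 12 arrays left out singly, and that of Apaf1 without the 3 arrays of mixed sex-linked signal (−0.17, adjusted p = 0.138) or mutants 1 and 2 (−0.18, adjusted p = 0.112). Of 16 immediate-early and heat shock genes, 3 fell and 1 rose (median −0.12; camera adjusted p = 0.0389; adjusted p = 0.431 with an estimated correlation), with 4 falling and 1 rising over the list alone. Dusp1, a MAP kinase phosphatase, fell by 0.46 and the small heat shock protein Hspb1 by 0.38. This list did not pass with camera on ranks (adjusted p = 0.0744), with fry (adjusted p = 0.108) or with camera without control 6 and mutant 6 (0.0550). Its mean did not differ between genotypes beyond the spread of arrays (exact permutation p = 0.115, adjusted p = 0.159 over the lists). Its median was −0.19 without mutants 1 and 2. Of 22 tendon and connective tissue genes, 4 fell and 1 rose, with a median of 0.01 and a mean of −0.05 (camera adjusted p = 0.365), and 5 fell and 3 rose over the list alone. Thbs4, a matrix protein of tendon, fell by 0.45 (−0.38 and adjusted p = 0.0566 without the 3 arrays of mixed sex-linked signal) and Osr1, a factor of connective tissue, rose by 0.43.

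As a measure of RNA quality, the 3′ minus 5′ signal of β-actin was 0.40 ± 0.04 in controls and 0.44 ± 0.05 in mutants (exact permutation p = 0.11), and that of Gapdh 0.03 ± 0.04 and 0.06 ± 0.03 (exact permutation p = 0.271). The β-actin difference was largest on mutants 1 and 2 (0.49 and 0.50, other mutants 0.38 to 0.43), the arrays farthest from the controls on the first principal component. Their Gapdh differences, 0.07 and 0.03, did not stand out. Array medians differed by less than the spread between arrays (exact permutation p = 0.985). Both sexes were present in each group, and none of the 4 measured sex-linked genes passed (camera adjusted p = 0.883 for the list; Xist 0.64 ± 1.52 SE, adjusted p = 0.848). Among named genes that passed, 38 had other probe sets. Of these 67 probe sets, 29 passed in the same direction, none in the opposite one, and 38 did not pass, 24 of them dimmer than the median of all probe sets. With the mean of a gene's probe sets in place of the brightest, Snap25 rose by 0.86, Gpr50 by 0.61 and Prrx1 by 0.39, while Smyd1 fell by 0.40, Myoz1 by 0.51, Fgfr4 by 0.49, Mb by 0.41, Tanc1 by 0.32 and Erbb3 by 0.33. With it Myod1 differed by −0.42 and lost its call (adjusted p = 0.0670), and Fgf4 passed with a fall of 0.57 (adjusted p = 0.000392).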

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

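The tests on muscle genes falling alike, on the spread of probe sets of 1 gene, on neuron markers and on sex-linked probe sets were chosen after the results were seen. An array was singled out when its gap to the nearest array of its group was a large part of the group's range, which chance gives in about 1 of 20 groups; 19 of 228 groups of 6 arrays met this.

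Control 1 was lowest of its group in several named genes. Its gap was 0.71 of the range for Myf6 (6.89, other controls 7.96 to 8.40), 0.666 for Sln, 0.648 for Klhl40, 0.634 for Tanc1 and 0.729 for Thbs4. It was also lowest in the mean of the excitation-contraction, neuromuscular junction and metabolism list (gap 0.654 of the range) and highest in the mean of the cranial mesenchyme list (0.645). Mutant 1 was lowest in Smad4, at 11.58 with the other mutants from 12.18 to 12.30 (0.836). Other single genes were Ankrd1, highest in mutant 5 (0.721), Ccne1, highest in mutant 6 (0.626), Jag1, lowest in control 3 (0.702), and Foxf1, lowest in control 2 (0.739). Control 2 was highest in the mean of SMAD-responsive genes (0.683) and in the β-actin 3′ minus 5′ difference (0.637).

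The 18S ribosomal RNA control probe sets were lowest in control 6 and mutant 6. For the 3′ probe set control 6 read 12.65 with the other controls at 13.74 or above, and mutant 6 lay below all other mutants, which read 13.55 or above (gaps 0.786 and 0.819 of the range). For the middle probe set the gaps were 0.821 and 0.835, and for the 5′ probe set mutant 6 stood out with 0.862. Outside the named genes, 135 of 9160 probe sets with no gene name here passed when every probe set was tested, 78 higher and 57 lower in the mutant, and the largest rise was 0.94 (adjusted p = 0.00414).

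Muscle genes were lower in the mutant. If muscle cells of every stage had been lost alike, the 7 muscle genes fixed by name should fall alike; their log2 fold changes had an SD of 0.57, from −0.70 for Cdh15 to −2.10 for Fgf6 (exact permutation p = 0.00216, the smallest possible). Probe sets of 1 gene, over 31 muscle genes that fell, had an SD of 0.19 around the mean of their gene; as a share of that mean it was 0.586, against 0.475 among the 7 genes, so an equal loss cannot be told apart from an unequal one where probe sets scale a change unequally. Lower RNA integrity was tested with the β-actin 3′ minus 5′ difference as a covariate, after which the sarcomere median was −0.84 and 39 of 51 members still fell. This argues against RNA integrity as the whole cause, while a loss of muscle cells, equal or not, and lower expression per cell, which the Smad4 genotype could bring about, stay open.

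Neuron markers were higher in the mutant. A lower share of muscle RNA would raise all other cell types alike, but the neuron list rose by 0.69 more than the mean of the endothelium, erythroid and macrophage lists within arrays (exact permutation p = 0.00433), and by 0.42 more than the mean of the epithelium, mesenchyme and cartilage lists, which also rose (exact permutation p = 0.00649). The neuron list was picked as the one that rose most, and the endothelium, erythroid and macrophage lists had moved little. The p values do not allow for that choice. More nerve or ganglion tissue in the mutant samples cannot be told apart from a change within neurons, since Schwann and glial markers had a median of 0.048 (0.0176 without control 5 and 0.081 without mutant 1) with members from −0.59 to 1.00. Central nervous tissue carried over would raise its genes on the mutant arrays, but its 18 genes gave no sign of this. They differed by −0.18 (Lhx5) to 0.07 (Neurod4), with a median of −0.0572 and none passing. A small carry-over stays open, since dim probe sets understate a rise. Only 2 of the genes lay above the median level of all probe sets in controls, where means ran from 3.11 to 6.79. Smad4 genotype remains an untested biological explanation, and dissection may differ between embryos.

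On 3 arrays Xist and Y-linked genes were both above the level of the opposite sex. Control 3 read 12.40 for Xist with 6.03 for the Y-linked Eif2s3y, which lay from 3.14 to 4.01 on the other arrays with high Xist. The Y-linked Kdm5d (5.22, those arrays 2.87 to 3.82) and Uty (4.68, those arrays 3.14 to 4.08) were raised on control 3 too. Mutants 4 and 6 read 8.73 and 7.88 for Xist, against at most 6.65 on the other male arrays. Their Y-linked genes were near male level, with Uty (7.70 and 7.55) below the other male arrays (7.86 to 8.13). RNA of both sexes in the 3 samples may account for this, and was tested on Xist probe sets that had not shown the pattern. Of 4 readings, 50% lay beyond the male arrays by over 0.5 on the log2 scale, both in mutant 4. Mutant 6 read 5.06 and 4.19 on these probe sets, with the male arrays at most 4.57 and 4.19. The first of its readings thus fell only just short of that limit. No Y-linked probe set other than those that showed the pattern separated the sexes well enough to test control 3. The test therefore did not settle whether RNA was mixed in all 3 samples. No biological explanation was tested.

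Other groupings of the arrays were compared with the real one. Of 100 of the 462 splits into 6 and 6, the real one included, 1 gave as many passing genes, the real one with 2020; the highest of the others gave 96. For genes with a fold of at least 1.5 the same count was 1 of 100, with 395 for the real split and 47 for the highest other. The split with 96 genes was the real one with control 1 and mutant 2 exchanged, and the next highest count was 2. Counts as large as the real ones were thus rare among the splits drawn. The splits cannot speak to a litter or batch that follows genotype.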

How the results depend on the processing

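Leaving out 3 sets of arrays was chosen after the data were seen; the other alternatives were set before the data were examined. Over those that keep all arrays, the total ran from 1394 (unequal-variance test) to 2432 (every probe set, counting probe sets). It was 2010 after quantile normalisation with 1868 genes shared, a weak check since RMA had already made the arrays nearly alike in distribution. Genes higher with a fold of at least 1.5 fell to 77 with the mean of a gene's probe sets, and with every probe set 594 probe sets had that fold, 403 of them lower. Without control 3, mutant 4 and mutant 6 the counts were 836 in all, 440 higher and 396 lower (806 shared with the 2020). Without mutants 1 and 2 they were 875, 379 and 496 (850 shared), with 55 higher at a fold of 1.5. Fewer samples were tested in both. Without control 6 and mutant 6, which leaves as many arrays as without mutants 1 and 2, 1890 genes passed, 1116 higher and 774 lower. The number of arrays alone thus does not account for the drop without mutants 1 and 2. For control 3, mutant 4 and mutant 6, whether the arrays themselves matter was not tested. Leaving out each array gave totals from 1398 to 2103 and from 733 (without mutant 1; 763 without mutant 2) to 1209 genes higher. The replicate numbers were not taken to pair the samples, since replicate 3 (−0.06) missed the correlation over 0.1 in their deviations that was required of every pair, though the other 5 exceeded it. With the number as a block 1932 genes passed, 1663 of them shared, Hba-x also passed (−0.28, adjusted p = 0.0391), and 7 of 12 arrays correlated best with their own number, a hint from the data and not from the design.

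With an estimated correlation the myogenic progenitor list (median −0.42, adjusted p = 0.179) and the regulatory factor list (−0.56, adjusted p = 0.0555) no longer passed. With it 4 of 25 lists passed, against 15 with the preset one and 14 with fry. Leaving out 1 array ended the call of the erythroid list in 7 of 12 cases and of the immediate-early list in 6. The fusion list passed with dim probe sets left out (−0.0166, adjusted p = 0.0451) and without mutants 1 and 2 (−0.0261, adjusted p = 0.0335), had a median of 0.00202 without control 6 and mutant 6, and ran from −0.0536 to 0.00607 over single arrays left out. Medians near 0 changed sign. The TGF-β and BMP list was at −0.00487 with the mean of probe sets and −0.000973 without mutants 1 and 2 (−0.00157 to 0.0326 over single arrays). The tendon list was at −0.00746 after quantile normalisation, −0.013 with the mean of probe sets and −0.0315 without mutants 1 and 2 (−0.013 to 0.0408 over single arrays). The Notch list was at −0.0157 with the mean of probe sets, −0.035 without the mixed arrays and −0.0126 without the low 18S arrays (−0.0109 to 0.0248 over single arrays). The sex-linked list was at 0.22 with the sex covariate and 1.02 without mutants 1 and 2 (−0.67 to 0.34 over single arrays), and Xist at −0.57 without them (−0.00965 to 1.42 over single arrays). The cause was not tested. Of 72 named genes that passed, 54 passed in every alternative that held their probe set (Aldh1a1, Calcb, Cdhr1, Dbx1 and Snap25 were not among those left after dim ones were dropped), and 0 changed direction. Csf1r, Myod1 and Bcl2l11 lost their calls repeatedly (adjusted p = 0.0601, 0.134 and 0.0659 in the unequal-variance test, which also ended those of 2310002L09Rik, Myf6, Gpr50, Foxd4 and 2610528A11Rik at 0.0504 to 0.0916). Dim probe sets limit what can be seen below 6.13.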

Other observations

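The lists in this part, and all tests on them, were chosen after the largest changes had been seen; their adjusted p values run over these 5 lists. Collagens outside the earlier lists changed in both directions. Of 20 measured, 4 fell and 1 rose (median 0.01; camera adjusted p = 0.0689), 4 and 1 over the list alone. Those that fell were Col22a1 (−1.60 ± 0.18 SE), Col19a1 (−1.50 ± 0.26), Col24a1 (−0.50 ± 0.13) and Col25a1 (−0.31 ± 0.07), and the fibrillar Col5a2 rose by 0.23 ± 0.05. The basement membrane collagens Col4a1 and Col4a2 differed by 0.06 and 0.04 and did not pass.

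Genes of axon guidance and of autonomic neurons were higher on balance. Of 23 axon guidance genes, the netrin receptors Dcc (0.98 ± 0.12), Unc5d (0.94 ± 0.17) and Unc5c (0.52 ± 0.12) rose with the repellent Sema3a (0.43 ± 0.09), while Sema3e fell by 1.28 ± 0.23 (camera adjusted p = 0.0127; adjusted p = 0.151 with an estimated correlation). Of 17 autonomic neuron genes 5 rose and none fell (median 0.25; camera adjusted p = 2.84e-05; adjusted p = 0.151 with an estimated correlation). They were Chgb, a granin of secretory granules (0.96 ± 0.11), Phox2a, a factor of autonomic neurons (0.82 ± 0.12), the nicotinic receptor subunit Chrna3 (0.50 ± 0.11), Hand2 (0.38 ± 0.08) and Th, tyrosine hydroxylase (0.23 ± 0.07). Neuron markers (median 0.71) and cranial mesenchyme markers (0.37) lay higher in the same mutant arrays. The autonomic list shares 3 genes with the earlier lists, among them Hand2, also a mesenchyme marker. The neuropeptide Vip (0.94 ± 0.32, adjusted p = 0.0769) and Dbh (−0.15, adjusted p = 0.292) did not pass. The central nervous list had a camera adjusted p of 0.0435 (0.253 with an estimated correlation), with a median of −0.06.

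Retinoid genes moved in opposite directions. Aldh1a1 rose by 1.67 ± 0.24 while Aldh1a3, another enzyme that makes retinoic acid, fell by 1.39 ± 0.29 (adjusted p = 0.00734). Aldh1a2, of the same gene family, differed by −0.72 ± 0.23 and fell just short of passing (adjusted p = 0.0557). In controls Aldh1a1 was dim, at 4.80, while Aldh1a2 and Aldh1a3 read 8.16 and 9.18. Rarb differed by −0.13 (adjusted p = 0.665). Of the degrading enzymes, Cyp26b1 rose by 0.67 ± 0.12 and Cyp26a1 fell by 0.37 ± 0.07. Of 15 measured, 4 rose and 3 fell (4 and 4 over the list alone), the others being Cyp1b1 (0.87) and Dhrs3 (0.22) among rises and the retinol carrier Rbp4 (−0.58) among falls. The list had a camera adjusted p of 0.879 (0.874 with an estimated correlation).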
